A study of Homo sapiens with 12 samples.

How the data were processed

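The data were 12 QuantSeq 3′ mRNA libraries of HepG2 cells, 3 for each of 4 culture media, per the labels. Cells were grown and seeded in EMEM in 6-well plates and 24 h later received LGDMEM, HGDMEM, EMEM or Plasmax for 96 h, with a change of medium at 48 h and 10% heat-inactivated serum throughout, per the labels' protocols. RNA was extracted with a commercial kit. The submitters' processing notes name the hg19/GRCh37 genome build and the tools FastQC 0.72, cutadapt 1.16, STAR 2.7.5b, featureCounts 1.6.3 and limma 3.40.6, without giving their role or order.

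The authors deposited 1 table of whole-number counts per gene with 11546 rows, in which no normalization is stated and the values are raw counts from their range and totals. The table had been filtered on low counts before deposit by a rule that is not stated, since the third highest CPM of each row was at least 2.51 while the fourth highest could be 0. The deposited totals of 4131093 to 6015796 counts per library are therefore not the full depth. Of the rows, 601 had no gene symbol and held 2.92% to 3.71% of a library's counts. They were left out of library sizes and tests, leaving 10945 rows and totals of 3995365 to 5840057. The files identify genes by symbol alone, 17 symbols look like dates, 5 symbols stand on 2 rows that were tested separately, and no coordinates are given because the reference available is of another build. Column names carried the medium and the replicate number, and 0 columns belonged to other samples.

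Computed from the deposited counts, differences were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test on TMM-scaled counts of all 12 libraries without a block, with Benjamini-Hochberg adjustment at 0.05. The low-count filter of edgeR removed 0 of the 10945 genes. The biological coefficient of variation was 0.215, with 8 residual and 10.4 prior degrees of freedom. CPM values use TMM-scaled library sizes, SE values are the log2 fold change divided by the square root of F, and list levels are means of log2 CPM with a prior count of 2. The 6 pairwise comparisons and 1 test over the 4 media were made. For genes with no read in one of the media compared, bounds used a floor of 3 counts over the medium's libraries, which covers counting error only, and list medians moved by at most 0.0616 when such genes were set to their bound (11 pairs of list and comparison had such members). That shift took the ATF4 list from 0.48 to 0.41 between LGDMEM and EMEM.

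Gene lists were fixed before the data were examined, 28 in number with 687 members, of which 589 were measured. They were tested with camera at a preset correlation of 0.01, adjusted within a comparison, and again with the correlation estimated from the data and with fry (limma 3.58.1), which does not compare a list with other genes. The lists were iron uptake and handling, iron storage, export and BMP-hepcidin axis, haem and iron-sulphur cluster synthesis, HIF targets, glycolysis, glucose-responsive ChREBP targets and gluconeogenesis, cholesterol synthesis and uptake, fatty acid and triglyceride synthesis, fatty acid oxidation and PPARA targets, ATF4 amino acid response, endoplasmic reticulum chaperones, NRF2 targets, selenoproteins, metallothioneins and zinc export, ferroptosis regulators, cell cycle and DNA replication, p53 targets, mature hepatocyte, hepatoblast and mesenchymal genes, urea cycle, purine and pyrimidine synthesis, respiratory chain, cytosolic ribosomal proteins, acute phase proteins, AHR, PXR and CAR targets, and leukocyte and endothelial or stromal markers. Genes named in the text were chosen by a rule also fixed beforehand. It takes the 7 largest rises and falls (4 for Plasmax against LGDMEM and against HGDMEM) among genes past the threshold with a mean of at least 10 CPM and no overlap between the groups, and up to 3 called members of each list past its threshold. TFRC, FTH1, FTL, HAMP, SLC40A1, HMOX1, TXNIP, ALB and AFP are always given, and any other gene named was chosen after its values were seen.

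Replicate numbers are shared by the media, so it was checked whether libraries of the same number deviate together. Over all genes tested no comparison had a correlation above 0.1 for all 3 numbers. Over 4366 genes with a mean log2 CPM above 5, HGDMEM against EMEM (0.186, 0.11 and 0.124) and HGDMEM against LGDMEM (0.246, 0.165 and 0.21) did, and these are called paired. Their main results still come from the fit without a block, which leaves the pairing out. LGDMEM against EMEM had 0.325, 0.193 and −0.0121, so number 3 alone failed and pairing there is unclear. Library names in the labels put Plasmax 1 last, so Plasmax numbers may not match those of the other media, and nothing was crossed. The block was an alternative fit for every comparison. Other alternatives were RLE, upper-quartile and library-size scaling, a stricter filter (mean of at least 5 CPM, 9380 genes), DESeq2 1.42.0, limma voom, an adjusted p of 0.01, fits to the libraries of the compared media alone, and leaving out each library in turn. Chosen after seeing the data were the inclusion of rows without a symbol, the block within HGDMEM pairs, the closer look at lists without LGDMEM 1 or LGDMEM 3, and the counts of called list members without each library.

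The tests per gene were tested on simulated data drawn from the real means with known changes. For Plasmax against EMEM with 10770 genes tested, edgeR recovered 12 of 67 genes changed 1.5-fold, 37 of 67 changed 2-fold and 57 of 66 changed 4-fold, with 6 false calls. Far fewer genes were changed there than the 2417 called in the real comparison. Fewer true changes make the adjusted threshold stricter, so these shares do not carry over to the real comparison. Replicate pairs within a medium differed with a chi-square per degree of freedom of 7.10 to 22.2 and a Pearson correlation of log2 CPM across genes, which are not independent replicates, of 0.941 to 0.963, and LGDMEM 1 and LGDMEM 3 differed most.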

Results

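HepG2, an established human liver cancer line used as a model of hepatocytes, was profiled by 3′ mRNA sequencing in 4 culture media. The cells were kept and seeded in EMEM and after 24 h were moved to EMEM, DMEM with low glucose (LGDMEM), its version with high glucose (HGDMEM) or Plasmax, a medium formulated after human plasma. All media contained 10% heat-inactivated serum, were renewed at 48 h, and the cells were harvested at 96 h. Each medium had 3 libraries, 12 in all. The deposited counts per library summed to between 4131093 and 6015796, of which 3995365 to 5840057 fell on 10945 rows with a gene symbol. These totals are not full sequencing depth, since rows with low counts had been removed before deposit. Levels are given in CPM, counts scaled to library size, as mean ± SD with n = 3. Nothing in the labels says that the replicates of a medium came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

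The study concerns iron availability and hepatocyte fate, and the comparison here is of the transcriptomes of cells in the 4 media. Expression differed among the media for 2506 of 10945 genes (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05), and 2481 of these were also called in a comparison with Plasmax. Plasmax differed from EMEM in 2417 genes, from LGDMEM in 2321 and from HGDMEM in 2947. These were 22.1%, 21.2% and 26.9% of the genes tested, so most lists would hold some called members in these comparisons. The other 3 media differed from each other in few genes, with 8 between LGDMEM and EMEM, 18 between HGDMEM and EMEM and 7 between HGDMEM and LGDMEM. The first principal component held 37.1% of the variance and separated Plasmax, whose libraries lay between 52.9 and 59.4, from all others, which lay between −29.0 and −3.47. LGDMEM 3 stood apart on the second component at −51.8, where the other 11 libraries lay between −11.0 and 14.7.

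**Figure D1:**
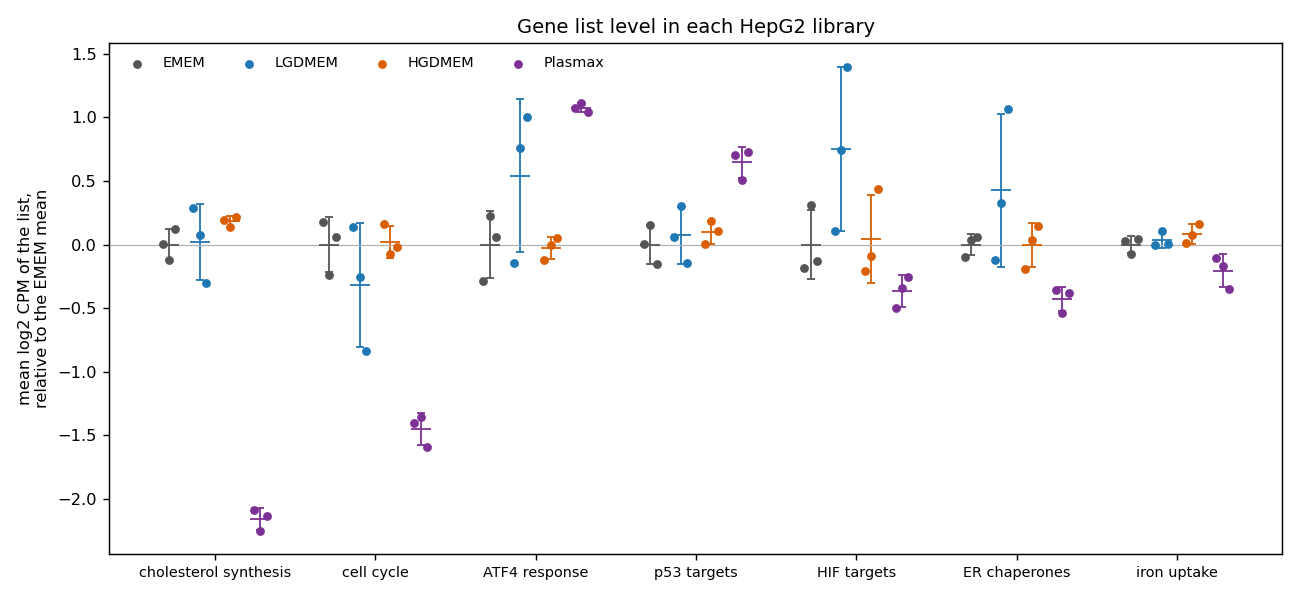
Level of 7 gene lists in each library, as the mean log2 CPM of the list's measured genes relative to the EMEM mean (vertical axis), for the 4 media (colours). Points are libraries, horizontal bars are means and error bars are SD with n = 3. The cholesterol list lay between −2.25 and −2.08 in the Plasmax libraries, and the HIF target list ranged from 0.11 to 1.40 among the LGDMEM libraries.

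Cells in Plasmax had far lower expression of the cholesterol synthesis and uptake genes than cells in EMEM. Of 24 measured members 22 fell and none rose, with a median log2 fold change of −2.36. ACAT2, an acetoacetyl-CoA thiolase, went from 558.0 ± 79.7 CPM in EMEM to 52.5 ± 11.6 CPM in Plasmax (log2 fold change −3.41, SE 0.21, adjusted p = 2.89e-08). The falls included MVK (mevalonate kinase) at −3.08, the sterol demethylation enzyme MSMO1 at −3.07 and the squalene synthase FDFT1 at −2.37. The members not called were PMVK at −0.29 and HSD17B7 at −0.32. Adjusted over the list alone, the count was also 22. The list test (camera with a preset correlation of 0.01, Benjamini-Hochberg adjustment over 28 lists) gave an adjusted p of 1.07e-56, and the call held with an estimated correlation, with adjusted p = 0.00539.

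Fatty acid and triglyceride synthesis genes were also lower in Plasmax, with 9 of 19 members down and 1 up (adjusted over the list alone, 10 down and 1 up). The desaturases FADS2, FADS1 and SCD fell, with log2 fold changes of −3.19, −2.42 and −1.74, and SCD went from 1243 ± 39.0 to 372.4 ± 32.6 CPM. AGPAT2, which acylates lysophosphatidic acid, was the member that rose, by a log2 fold change of 2.48. The list test gave an adjusted p of 4.11e-06, which was lost with an estimated correlation (adjusted p = 0.175 with an estimated correlation).

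All 34 measured cell cycle and DNA replication genes fell in Plasmax relative to EMEM, with a median log2 fold change of −1.47. The mitotic kinases PLK1 and AURKA fell, with log2 fold changes of −1.41 and −1.64, and UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, went from 98.97 ± 19.3 to 25.14 ± 0.79 CPM (log2 fold change −1.97, SE 0.17, adjusted p = 2.05e-07). Adjusted over the list alone the count was again 34. The list's adjusted p was 3.84e-34, and its call was lost with an estimated correlation (adjusted p = 0.175 with an estimated correlation). Targets of p53 were higher, with 11 of 24 up and 0 down (12 up and 1 down adjusted over the list alone). CDKN1A, the cell cycle inhibitor p21, rose by a log2 fold change of 1.54 (SE 0.16), RRM2B by 1.41 and ZMAT3 by 1.24. The p53 list passed at an adjusted p of 1.21e-05 and was lost with an estimated correlation (adjusted p = 0.23 with an estimated correlation).

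The ATF4 amino acid response, a set of amino acid synthesis, transport and tRNA charging genes, was higher in Plasmax than in EMEM. It had 24 of 36 members up, 0 down and a median log2 fold change of 0.96 (28 up and 1 down adjusted over the list alone). The cystine transporter subunit SLC7A11 went from 111.9 ± 37.5 to 520.8 ± 51.4 CPM (log2 fold change 2.22, SE 0.26, adjusted p = 8.71e-06), the serine synthesis enzyme PSAT1 rose by 1.35 and the asparaginyl-tRNA synthetase NARS by 1.00. CHAC1, a glutathione-degrading enzyme noticed after its values were seen, had 0 reads in EMEM and 61 in Plasmax, which is at least 19.7-fold higher against a floor of 3 counts over the EMEM libraries. The list's adjusted p of 8.2e-15 was lost with an estimated correlation (adjusted p = 0.303 with an estimated correlation). Endoplasmic reticulum chaperones went the other way, with 8 of 21 down and 0 up (the same counts adjusted over the list alone). CALR (calreticulin) at −1.16, CRELD2 at −1.19 and SEC61B, a subunit of the translocon, at −0.65 were among those that fell. That list's adjusted p was 0.00536 (adjusted p = 0.574 with an estimated correlation).

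Among iron genes, the transferrin receptor TFRC, which takes up transferrin-bound iron, went from 318.9 ± 14.98 CPM in EMEM to 131.0 ± 7.07 CPM in Plasmax (log2 fold change −1.28, SE 0.11, adjusted p = 2.68e-07). HAMP, which encodes the iron hormone hepcidin, went from 44.25 ± 4.00 to 7.06 ± 3.57 CPM (log2 fold change −2.64, SE 0.37, adjusted p = 5.92e-05). Ferritin light chain FTL fell by 0.43, while the heavy chain FTH1 was not called at 0.31 (SE 0.13, adjusted p = 0.108). The ferritin genes have processed pseudogenes, so their counts are less certain. The iron exporter SLC40A1 at 0.25 (SE 0.31) and the haem oxygenase HMOX1 at −0.28 (SE 0.23) were not called. In the list of iron uptake and intracellular iron handling 4 of 16 members fell and none rose (0 up and 6 down adjusted over the list alone), but the list did not pass (adjusted p = 0.145). The 4 were TFRC, SLC39A14, NCOA4 and ACO1, the last 3 named after their values were seen. The list of iron storage, export and the BMP-hepcidin axis had 3 up and 6 down of 17 (adjusted p = 0.223), and haem and iron-sulphur cluster synthesis had 3 up and 2 down of 26 (adjusted p = 0.504). The count adjusted over the list alone was unchanged for both lists. Of all genes tested 22.1% were called, so 3 up and 2 down of 26 is no more than genes in general showed. In haem and iron-sulphur synthesis ISCU, LYRM4 and FDXR rose and CPOX and BOLA3 fell, and in the storage list BMPR2, ACVR1 and NEO1 rose, all named after their values were seen.

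**Figure D2:**
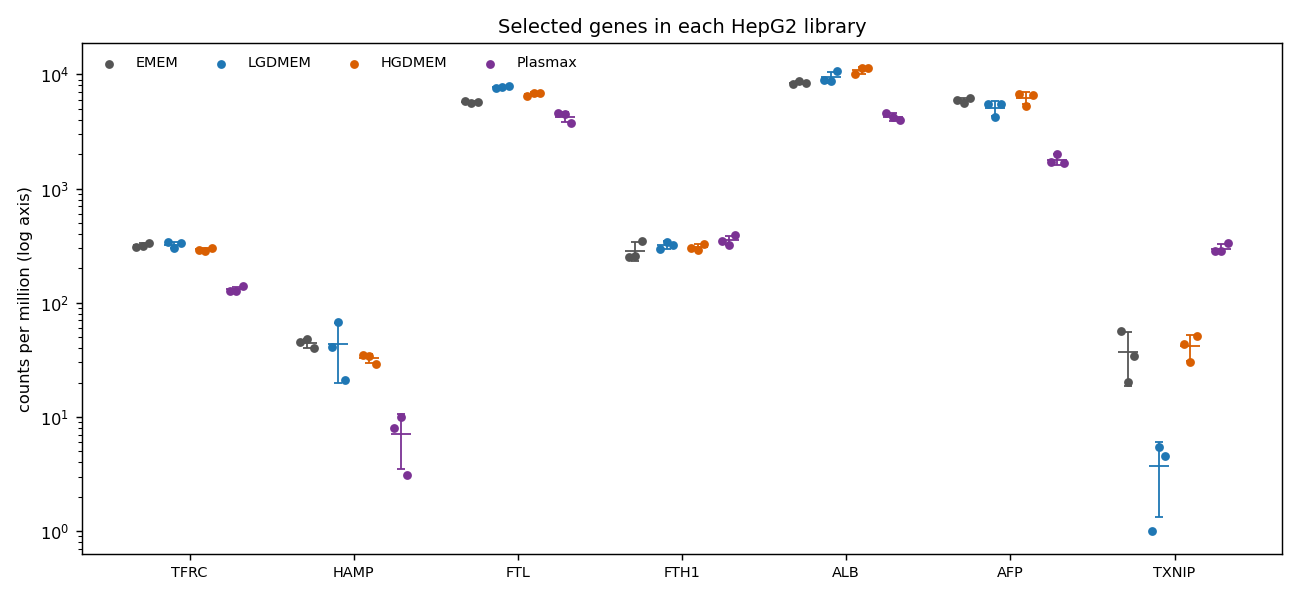
Levels of 7 genes in each library in CPM on a log axis, for the 4 media (colours), with points for libraries, horizontal bars for means and error bars for SD with n = 3. TFRC, HAMP, FTL, ALB and AFP were lower in every Plasmax library than in every library of the other media, and TXNIP was below 6 CPM in each LGDMEM library.

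Mature hepatocyte genes were lower in Plasmax than in EMEM, with 9 of 26 down and 2 up (10 down and 2 up adjusted over the list alone). ALB (albumin) went from 8453 ± 261 to 4259 ± 338 CPM (log2 fold change −0.99, SE 0.10, adjusted p = 1.35e-06), the iron carrier transferrin TF fell by 1.32 and the apolipoprotein APOH fell by 1.17. SERPINA1 and AMBP, named after their values were seen, rose by log2 fold changes of 0.57 and 0.42. AFP (alpha-fetoprotein), made by fetal liver and hepatoma cells, fell by 1.73. The mature hepatocyte list passed at an adjusted p of 0.00816 and was lost with an estimated correlation (adjusted p = 0.395 with an estimated correlation), while hepatoblast and progenitor genes did not pass, with 6 up and 3 down of 13, also adjusted over the list alone (adjusted p = 0.437). The summed CPM of the mature hepatocyte genes was 31955 ± 443 in EMEM and 23545 ± 1131 in Plasmax. That of 4 leukocyte markers, of which LYZ made 99.5%, was 2980 ± 320 and 2105 ± 121, and that of 2 endothelial and stromal markers was 12.2 ± 0.91 and 11.2 ± 0.64. Mitochondrial transcripts took 13.5 ± 1.00% of the counts in Plasmax and 11.4 ± 1.11% in EMEM.

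Metallothioneins and zinc export genes had 6 of 9 members down and 1 up (the same counts adjusted over the list alone). MT1G at −2.71, MT1F at −1.82 and MT1E at −0.68 fell, and MT2A, named after its values were seen, rose by a log2 fold change of 0.38. These genes are near-identical copies, so reads could be divided among them. The list's adjusted p was 0.00444 (adjusted p = 0.303 with an estimated correlation), and 3 members were down without EMEM 1. Glycolysis genes had 7 of 20 down and 1 up (9 down and 1 up adjusted over the list alone). ALDOC went from 19.5 ± 5.31 to 2.31 ± 0.89 CPM, SLC2A3, a glucose transporter, fell by 1.10 and the aldolase ALDOA fell by 0.85, whereas the glucose transporter SLC2A1, named after its values were seen, rose by 0.55. The glycolysis list passed at an adjusted p of 0.0181 (adjusted p = 0.555 with an estimated correlation) and no longer passed without Plasmax 1 (adjusted p = 0.0542). Without Plasmax 1 or EMEM 3, 4 of its members were down. TXNIP, a glucose-induced gene, rose from 37.14 ± 18.6 to 298.0 ± 28.0 CPM (log2 fold change 3.02, SE 0.31, adjusted p = 1.91e-06).

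The other lists did not pass between Plasmax and EMEM, although members of most were called. In this comparison 22.1% of all genes tested were called, so a count near that share is what genes in general showed. HIF targets had 3 up and 5 down of 27 (adjusted p = 0.223), glucose-responsive and gluconeogenesis genes 5 up and 4 down of 17 (adjusted p = 0.223), NRF2 targets 4 up and 10 down of 26 (adjusted p = 0.283) and selenoproteins 4 up and 6 down of 19 (adjusted p = 0.504). Fatty acid oxidation and PPARA targets had 3 up and 6 down of 22 (adjusted p = 0.214), mesenchymal transition genes 7 up and 3 down of 14 (adjusted p = 0.145) and acute phase proteins 3 up and 2 down of 15 (adjusted p = 0.318). Mitochondrial respiratory chain genes had 2 up and 9 down of 43 (adjusted p = 0.214), cytosolic ribosomal proteins 5 up and 0 down of 48 (adjusted p = 0.283) and purine and pyrimidine synthesis 0 up and 4 down of 20 (adjusted p = 0.214). Urea cycle and amino acid catabolism genes had 3 up and 2 down of 20 (adjusted p = 0.504) and AHR, PXR and CAR targets 2 up and 2 down of 9 (adjusted p = 0.223). Ferroptosis regulators had 4 up and 5 down of 18, and their median of −0.15 and mean of 0.38 differed in sign (adjusted p = 0.678). Leukocyte markers had 1 up and 1 down of 4 (adjusted p = 0.921), and of 2 endothelial and stromal markers 1 fell (adjusted p = 0.627). Adjusted over the list alone, the counts up and down were 3 and 6 for HIF targets, 7 and 11 for NRF2 targets, 5 and 7 for selenoproteins, 4 and 6 for fatty acid oxidation, 4 and 2 for acute phase proteins, 2 and 0 for ribosomal proteins and 2 and 4 for AHR, PXR and CAR targets. They were the same as over all genes for the other lists. Among lists that passed, the median, the mean and the test had the same sign in all 6 comparisons.

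Among called genes with a mean of at least 10 CPM over the 2 groups and no overlap of their libraries, the largest rises in Plasmax relative to EMEM were in PAQR5 (log2 fold change 4.89), the protease inhibitor CSTA (4.26), the glucocorticoid-induced TSC22D3 (3.90), LAIR2 (3.77), the acute phase protein ORM1 (3.55), the cyclin-dependent kinase inhibitor CDKN2B (3.28) and TMEM59L (3.19). CSTA went from 3.98 ± 2.02 to 78.4 ± 18.2 CPM. ORM1 varied widely among the Plasmax libraries, at 247.2 ± 177 CPM, and shares reads with the near-identical ORM2. ORM2, named after its values were seen, went the other way at −2.30 (SE 0.54). How reads were divided between ORM1 and ORM2 was not tested, so the rise of ORM1 is uncertain. Besides lipid genes and ALDOC the largest falls by this rule included LOC107987373 (log2 fold change −3.14), whose call was lost in 5 of 17 alternative settings. In all, 1094 genes rose and 1323 fell, and 427 and 568 of them changed at least 2-fold. Without EMEM 1 the number that rose was 714. The genes called here included 7 with no read in one of the media, all of them at least 2-fold at the bound that 3 counts allow.

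TXNIP, which is induced by glucose, was the most reduced called gene in LGDMEM, at 3.68 ± 2.36 CPM against 37.14 ± 18.6 CPM in EMEM (log2 fold change −3.26, SE 0.39, adjusted p = 0.00126). CARHSP1 fell by 2.49 and C1D fell by 1.32 on the log2 scale, and SOBP, MXRA8 and FGB (fibrinogen beta chain) fell, at −0.90, −0.79 and −0.62. SAT2 rose from 49.66 ± 7.24 to 115.7 ± 4.47 CPM (log2 fold change 1.22, SE 0.15, adjusted p = 0.00126), and SDF2L1, an endoplasmic reticulum chaperone cofactor, by 1.47. These 8 genes were all those called, 2 up and 6 down by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The 6 genes other than TXNIP and SAT2 each lost their call in 7 to 9 of 17 alternative settings, and TXNIP in 2, limma voom and the fit to the 2 media alone. The count was 87 without LGDMEM 1, 3 without LGDMEM 2, 2 without EMEM 1, and 3 without EMEM 2 or without EMEM 3. The balance of directions was not stable, since 73.6% of the 87 genes rose, as did 66.7% of the 3 without LGDMEM 2, 53.3% of 15 with the replicate block and 52.3% of 65 with DESeq2.

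Stress-related lists ranked higher in LGDMEM than in EMEM although almost none of their members were called singly. ATF4 amino acid response genes had a median log2 fold change of 0.48 with 0 of 36 called (12 up adjusted over the list alone, list adjusted p = 1.04e-15, adjusted p = 0.302 with an estimated correlation). HIF targets had a median of 0.55 with 0 of 27 called (7 up adjusted over the list alone, list adjusted p = 8.36e-12, adjusted p = 0.302 with an estimated correlation). Endoplasmic reticulum chaperones had a median of 0.46 with SDF2L1 called of 21 members (7 up adjusted over the list alone, list adjusted p = 6.6e-09, adjusted p = 0.357 with an estimated correlation). Cell cycle genes had a median of −0.27 with 0 of 34 called, and 0 adjusted over the list alone (list adjusted p = 2.18e-07, adjusted p = 0.427 with an estimated correlation). Smaller list results were mesenchymal transition genes with a median of −0.27 (adjusted p = 0.000911, and adjusted p = 0.122 with an estimated correlation), glycolysis at 0.24 (adjusted p = 0.00262, and adjusted p = 0.402 with an estimated correlation) and ferroptosis regulators at 0.25 (adjusted p = 0.00322, and adjusted p = 0.122 with an estimated correlation). Urea cycle genes had a median of 0.28 (adjusted p = 0.0144, and adjusted p = 0.131 with an estimated correlation) and NRF2 targets one of 0.09 (adjusted p = 0.0374, and adjusted p = 0.402 with an estimated correlation). Adjusted over the list alone, these 5 lists had 0 up and 2 down, 1 up, 1 up, 1 up and 1 up in that order. No member was called in any of them over all genes tested, where unadjusted p fell below 0.05 for 866 genes, and DESeq2 called 65 genes in this comparison.

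The LGDMEM libraries differed widely in these lists. The HIF target level relative to the EMEM mean was 0.11 in LGDMEM 1, 0.75 in LGDMEM 2 and 1.40 in LGDMEM 3, and the ATF4 level was −0.14, 0.76 and 1.00. Endoplasmic reticulum chaperones stood at −0.12, 0.33 and 1.07, and cell cycle genes at 0.14, −0.25 and −0.83. Without LGDMEM 3 the chaperone list (adjusted p = 0.141), the cell cycle list (adjusted p = 0.368), glycolysis (adjusted p = 0.328), ferroptosis regulators (adjusted p = 0.0539) and urea cycle genes (adjusted p = 0.0735) no longer passed. The medians without LGDMEM 3 were 0.19 for ATF4, 0.08 for chaperones, −0.08 for the cell cycle, 0.12 for glycolysis and 0.08 for the urea cycle, and without LGDMEM 1 they were 0.79 for ATF4, 0.71 for chaperones, −0.49 for the cell cycle and 0.17 for NRF2 targets. The urea cycle median was 0.17 without EMEM 3. Without LGDMEM 1, 13 ATF4, 7 chaperone, 5 HIF, 4 ferroptosis, 2 NRF2, 1 glycolysis and 1 urea cycle genes were called higher in LGDMEM than in EMEM and 2 cell cycle genes lower, and the mesenchymal list no longer passed (adjusted p = 0.0528). The NRF2 list was lost without LGDMEM 2 (adjusted p = 0.57, median −0.00013), without EMEM 1 (adjusted p = 0.0645) or without EMEM 2 (adjusted p = 0.0741), and with the rows that have no symbol included (adjusted p = 0.0513). TFRC at 0.02 (SE 0.11), HAMP at −0.03 (SE 0.32), FTL at 0.43 (SE 0.09, adjusted p = 0.0926), FTH1 at 0.17, SLC40A1 at −0.46, HMOX1 at 0.56, ALB at 0.16 and AFP at −0.22 were not called.

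HGDMEM differed from EMEM in 18 genes, of which 4 rose and 14 fell. ANGPTL8, a hepatokine induced by feeding, went from 4.19 ± 2.05 to 19.2 ± 6.82 CPM (log2 fold change 2.18, SE 0.39, adjusted p = 0.0284). SAA4 rose by 2.07, SAT2 by 0.90 and the isocitrate dehydrogenase IDH1 by 0.53. CYR61, a matricellular protein, fell by 1.83 on the log2 scale. MATN3 at −1.41, CPLX2 at −1.03 and the actin-binding TAGLN at −0.95 fell as well, and the p53 target BBC3 fell by 1.00. SAA4 belongs to a family of similar genes. CPLX2 (109.0 ± 6.12 against 222.6 ± 23.5 CPM, SE 0.13, adjusted p = 0.00194) kept its call in all 18 alternative settings, MATN3 lost it in 2, and the other genes named here in 6 to 10. Left out in turn, each of the 6 libraries brought the count of 18 down to 2 (HGDMEM 1), 1 (HGDMEM 2), 6 (HGDMEM 3), 7 (EMEM 1), 4 (EMEM 2) and 4 (EMEM 3). The 18 genes and the list tests of this comparison come from the fit without the block, which leaves the pairing out. The libraries met the pairing rule, and with the replicate block the count was 23. In fits to the 2 media alone it was 73 with the block and 43 without it.

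Mesenchymal transition genes ranked lower in HGDMEM, with CYR61, TAGLN and TGFBI down among 14 (0 up and 4 down adjusted over the list alone). Without any one of the 6 libraries 0 members were called by edgeR, while the list still passed (unadjusted p fell below 0.05 for 703 to 840 genes, and other tools were not run without a library). The list's adjusted p was 8.02e-05, lost with an estimated correlation (adjusted p = 0.0973 with an estimated correlation). Cytosolic ribosomal proteins had a median log2 fold change of −0.16 with 0 of 48 called (adjusted p = 7.15e-05, and adjusted p = 0.567 with an estimated correlation). Cholesterol synthesis genes at 0.15, selenoproteins at 0.11, respiratory chain genes at 0.07 and urea cycle genes at 0.18 passed at an adjusted p of 0.0345 each with no member called. With an estimated correlation the adjusted p was 0.576, 0.159, 0.503 and 0.159 in that order. Adjusted over the list alone 0 members were called in each of the 5 lists other than the mesenchymal genes, where unadjusted p fell below 0.05 for 830 genes over all tested and DESeq2 called 68. These 4 lists each lost their call without any of several libraries. Without HGDMEM 1 the adjusted p was 0.0808 for cholesterol, 0.073 for the respiratory chain and 0.0651 for the urea cycle, and without HGDMEM 2 it was 0.0576 for the urea cycle. Without HGDMEM 3 it was 0.122 for cholesterol, 0.167 for selenoproteins and 0.191 for the respiratory chain. Without EMEM 1 it was 0.0969 for cholesterol, 0.122 for the respiratory chain and 0.0711 for selenoproteins and the urea cycle, and without EMEM 2 it was 0.339, 0.235, 0.0855 and 0.0598 for cholesterol, the respiratory chain, selenoproteins and the urea cycle. With the stricter filter on low counts cholesterol was lost too (adjusted p = 0.0701). Medians that moved were cholesterol, at 0.22 without HGDMEM 2 and 0.27 without EMEM 3, the respiratory chain at 0.12 without EMEM 3, selenoproteins at 0.17 without HGDMEM 1 and the urea cycle at 0.12 without HGDMEM 2. Of the iron genes, TFRC at −0.12 (SE 0.11), HAMP at −0.44 (SE 0.32), FTL at 0.23, FTH1 at 0.11, SLC40A1 at −0.53 and HMOX1 at 0.20 were not called, nor were TXNIP at 0.18, ALB at 0.37 and AFP at 0.07.

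Between the DMEM formulations, which the labels distinguish by their glucose content, TXNIP was higher in the high-glucose medium, at 41.73 ± 10.7 against 3.68 ± 2.36 CPM in LGDMEM (log2 fold change 3.44, SE 0.39, adjusted p = 0.00057). C1D rose from 19.4 ± 1.38 to 54.9 ± 2.91 CPM. DDIT3, the stress transcription factor CHOP, fell by 2.24 on the log2 scale. The cytokine IL11 at −1.95, the glucose transporter SLC2A3 at −1.07, CPLX2 at −0.91 and the cytoskeletal actin ACTG1 at −0.65 also fell. These 7 genes, 2 up and 5 down, were all those called, and ACTG1 shares sequence with other actins. Of 18 alternative settings SLC2A3 lost its call in 9, DDIT3 in 8, IL11 in 4, ACTG1 in 3, CPLX2 in 2 and TXNIP and C1D in 1 each. In fits to the 2 media alone, with and without the block, the 5 genes that fell all lost their calls. IL11 was also lost without HGDMEM 1, ACTG1 without HGDMEM 2 and C1D without LGDMEM 2. With the replicate number as a block the count was 15 in place of 7, and in fits to the 2 media alone it was 3 with the block, of which 66.7% rose, and 2 without it, of which 100% rose. It was 118 without LGDMEM 1 and 4 without LGDMEM 2. Of the 5 genes called without HGDMEM 1, 60% rose.

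The ATF4, HIF, chaperone and glycolysis lists ranked lower in HGDMEM than in LGDMEM, and cell cycle genes ranked higher. ATF4 genes had a median of −0.52 with DDIT3 called of 36 (0 up and 16 down adjusted over the list alone, list adjusted p = 2.58e-17, adjusted p = 0.316 with an estimated correlation). HIF targets had a median of −0.65 (7 down adjusted over the list alone, list adjusted p = 2.21e-12, adjusted p = 0.316 with an estimated correlation), chaperones one of −0.54 (9 down adjusted over the list alone, list adjusted p = 1.03e-08, adjusted p = 0.433 with an estimated correlation) and cell cycle genes one of 0.28 (0 adjusted over the list alone, list adjusted p = 1.87e-08, adjusted p = 0.476 with an estimated correlation). Glycolysis genes had a median of −0.35 with SLC2A3 called of 20 (3 down adjusted over the list alone, list adjusted p = 3.49e-06, adjusted p = 0.316 with an estimated correlation). Glucose-responsive genes had a median of 0.23 with TXNIP called of 17, also when adjusted over the list alone (list adjusted p = 0.00386, adjusted p = 0.153 with an estimated correlation). Ribosomal proteins at −0.16 (adjusted p = 0.000816, and adjusted p = 0.596 with an estimated correlation), ferroptosis regulators at −0.18 (adjusted p = 0.00527, and adjusted p = 0.153 with an estimated correlation), NRF2 targets at −0.08 (adjusted p = 0.0369, and adjusted p = 0.476 with an estimated correlation) and AHR, PXR and CAR targets at 0.25 (adjusted p = 0.0442, and adjusted p = 0.316 with an estimated correlation) also passed. Adjusted over the list alone these 4 had 0, 2, 1 and 0 members down, none up, and none was called over all genes, where DESeq2 called 55 genes and unadjusted p fell below 0.05 for 860. Cholesterol synthesis genes did not pass (adjusted p = 0.0518, and adjusted p = 0.596 with an estimated correlation). They passed in 8 of 18 alternative settings, among them the replicate block (adjusted p = 0.045), and this rests on single libraries, with a median of 0.16 in the main fit, 0.35 without LGDMEM 1 (adjusted p = 0.000252) and −0.0044 without LGDMEM 3 (adjusted p = 0.7855).

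Single libraries decided several of these list results between HGDMEM and LGDMEM. Without LGDMEM 1, 14 ATF4, 7 chaperone, 5 HIF, 3 ferroptosis, 2 NRF2 and 2 glycolysis genes were called lower in HGDMEM and 3 cell cycle genes higher. The medians without LGDMEM 3 were −0.28 for ATF4, −0.35 for HIF targets, −0.11 for chaperones, −0.08 for glycolysis, −0.05 for ribosomal proteins, 0.05 for the cell cycle and −0.16 for NRF2 targets. Without LGDMEM 1 they were −0.84 for ATF4, 0.50 for the cell cycle, 0.36 for glucose-responsive genes and −0.15 for NRF2 targets. Without HGDMEM 1 the glucose-responsive median was 0.44 and that of NRF2 targets −0.04, without HGDMEM 2 ribosomal proteins stood at −0.09, glycolysis at −0.23 and NRF2 targets at −0.18, without HGDMEM 3 glucose-responsive genes at 0.14, and without LGDMEM 2 NRF2 targets at −0.05. Without LGDMEM 3 the chaperone (adjusted p = 0.152), cell cycle (adjusted p = 0.197) and ribosomal protein (adjusted p = 0.268) lists no longer passed. Ribosomal proteins were also lost without HGDMEM 2 (adjusted p = 0.0516). NRF2 targets were lost without LGDMEM 2 (adjusted p = 0.651), HGDMEM 1 (adjusted p = 0.254) or HGDMEM 3 (adjusted p = 0.0687), and AHR, PXR and CAR targets without LGDMEM 1 (adjusted p = 0.39) or HGDMEM 2 (adjusted p = 0.184). With library size alone NRF2 targets were lost too (adjusted p = 0.0508), glucose-responsive genes were lost with limma voom (adjusted p = 0.107), and AHR, PXR and CAR targets with limma voom (adjusted p = 0.0758) or the stricter filter (adjusted p = 0.267). No iron gene was called, with TFRC at −0.14 (SE 0.11), HAMP at −0.41 (SE 0.33), FTL at −0.20, FTH1 at −0.06, SLC40A1 at −0.07 and HMOX1 at −0.36. ALB at 0.21 and AFP at 0.29 were not called either.

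Relative to LGDMEM, cells in Plasmax again had lower cholesterol synthesis genes, with 21 of 24 down, 0 up and a median log2 fold change of −2.31 (21 down adjusted over the list alone, list adjusted p = 3.34e-59). That call held with an estimated correlation, with adjusted p = 0.00588. ACAT2, MSMO1 and FDFT1 fell, with log2 fold changes of −3.58, −2.96 and −2.48. TXNIP rose from 3.68 ± 2.36 to 298.0 ± 28.0 CPM (log2 fold change 6.28, SE 0.39, adjusted p = 9.22e-09), the membrane protein CD109 rose by 4.22, SERPINE2, a serine protease inhibitor, by 3.63 and ZNF528-AS1 by 3.58. GSTA1, a glutathione transferase with near-identical relatives, fell by 5.03, and EPO (erythropoietin) at −4.87 and the glycolysis regulator PFKFB3 at −4.13 fell. ZNF528-AS1 is an antisense gene and its reads may include those of its partner.

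HIF targets were lower in Plasmax than in LGDMEM, with 12 of 27 down and 1 up (14 down and 1 up adjusted over the list alone, list adjusted p = 1.48e-05, adjusted p = 0.282 with an estimated correlation), among them FAM162A at −1.16. Their median was −1.08, against −0.63 without LGDMEM 3, where 9 were down, and −1.27 without LGDMEM 1, where 15 were down. Endoplasmic reticulum chaperones had 11 of 21 down and 0 up (16 down adjusted over the list alone, list adjusted p = 1.08e-08, adjusted p = 0.253 with an estimated correlation), with SDF2L1 at −2.66, CRELD2 at −2.16 and CALR at −1.46. The count was 7 without LGDMEM 3, where the median was −0.34 in place of −0.81, 7 without Plasmax 2 and 16 without LGDMEM 1. Cell cycle genes had 31 of 34 down (32 adjusted over the list alone, list adjusted p = 2.58e-22, adjusted p = 0.15 with an estimated correlation), among them CDC6 at −2.04, UBE2C at −1.66 and AURKA at −1.63. ATF4 genes had 11 up and 2 down of 36 (12 up and 2 down adjusted over the list alone, list adjusted p = 8.89e-05, adjusted p = 0.423 with an estimated correlation), with SLC7A11 up by 1.64, PSAT1 by 1.00 and NARS by 0.91, and no longer passed without LGDMEM 1 (adjusted p = 0.0707). The number up was 7 without LGDMEM 1, 17 without LGDMEM 3 and 7 without Plasmax 3. Targets of p53 had 9 of 24 up and 0 down, unchanged when adjusted over the list alone (list adjusted p = 6.85e-05, adjusted p = 0.15 with an estimated correlation), with RRM2B up by 1.76, CDKN1A by 1.42 and PHLDA3 by 1.19.

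Iron uptake and handling genes passed in this comparison, with 0 of 16 up and 5 down, unchanged when adjusted over the list alone (list adjusted p = 0.0309, adjusted p = 0.15 with an estimated correlation). TFRC fell by 1.30 (SE 0.11), and NCOA4, which directs ferritin to degradation, at −0.56 and the cytosolic aconitase and iron sensor ACO1 at −0.88 also fell. This list was lost without LGDMEM 2 (adjusted p = 0.0543) or Plasmax 3 (adjusted p = 0.0735), and 3 members were down without Plasmax 2 or Plasmax 3. ACO1 lost its call without Plasmax 2. HAMP fell by 2.61 (SE 0.37), FTL fell by 0.86 and HMOX1 fell by 0.84, the last losing its call in 3 of 17 alternative settings, while FTH1 at 0.14 and SLC40A1 at 0.71 were not called. Metallothioneins had 4 of 9 down (5 adjusted over the list alone, list adjusted p = 8.89e-05, adjusted p = 0.15 with an estimated correlation), among them MT1G at −3.07, MT1F at −1.94 and MT1E at −0.76. NRF2 targets had 4 up and 13 down of 26 (6 up and 13 down adjusted over the list alone, list adjusted p = 0.0296, adjusted p = 0.282 with an estimated correlation), with AKR1C2, one of several similar aldo-keto reductases, at −1.18 and the peroxiredoxin PRDX1 at −0.94, and 8 down without Plasmax 3.

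Mature hepatocyte genes had 5 up and 9 down of 26 between Plasmax and LGDMEM (5 up and 11 down adjusted over the list alone, list adjusted p = 0.00962, adjusted p = 0.271 with an estimated correlation), with APOH at −1.45, ALB at −1.15 and APOA2 at −0.94, and AFP fell by 1.51. Mesenchymal transition genes had 7 up and 2 down of 14 (8 up and 2 down adjusted over the list alone, list adjusted p = 0.000691, adjusted p = 0.125 with an estimated correlation), with the fibronectin gene FN1 up by 0.82 and the cadherin CDH2 by 1.00. Fatty acid synthesis genes had 1 up and 9 down of 19 (1 up and 10 down adjusted over the list alone, list adjusted p = 9.54e-07, adjusted p = 0.15 with an estimated correlation), with FADS2, FADS1 and SCD at −3.11, −2.29 and −1.84. Glycolysis genes had 1 up and 9 down of 20, unchanged when adjusted over the list alone (list adjusted p = 6.18e-05, adjusted p = 0.218 with an estimated correlation), with ALDOC at −3.87, SLC2A3 at −1.59 and SLC16A3 at −1.36. Respiratory chain genes had 1 up and 9 down of 43, unchanged when adjusted over the list alone (list adjusted p = 0.0309, adjusted p = 0.282 with an estimated correlation), with NDUFA9 at −0.67, ATP5F1C at −0.62 and ATP5F1B at −0.55. The NRF2 and respiratory chain lists were both lost without Plasmax 2 (adjusted p = 0.0576), NRF2 targets also without LGDMEM 2 (adjusted p = 0.145), and the respiratory chain without LGDMEM 1 (adjusted p = 0.0763). Glucose-responsive genes and urea cycle genes did not pass (adjusted p = 0.0547 each) but did in 5 of 17 alternative settings each. Of the 2321 genes called, 1038 rose and 1283 fell, with 390 and 553 changed at least 2-fold.

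Relative to HGDMEM, Plasmax cells showed 22 of 24 cholesterol synthesis genes down, 0 up and a median log2 fold change of −2.43 (23 down adjusted over the list alone, list adjusted p = 1.44e-53), and this call held with an estimated correlation, with adjusted p = 0.00624. MVK, ACAT2 and MSMO1 fell, with log2 fold changes of −3.75, −3.73 and −3.24. GSTA1 went from 35.3 ± 8.84 to 0.73 ± 0.10 CPM (log2 fold change −5.53, SE 0.49, adjusted p = 2.26e-07). Among called genes with a mean of at least 10 CPM over the 2 groups and no overlap of their libraries, the largest rises were in TSC22D3 (5.04), CD109 (4.86), the cytokine signalling inhibitor SOCS3 (4.07) and the EGF receptor ligand AREG (4.00). TXNIP rose by 2.84 although both media had it above 30 CPM in every library. TFRC at −1.16 (SE 0.11), HAMP at −2.20 (SE 0.37), FTL at −0.65, ALB at −1.36 and AFP at −1.80 fell, and FTH1 at 0.20, HMOX1 at −0.48 and SLC40A1 at 0.78 were not called. Iron uptake and handling genes had 6 of 16 down and 0 up, also adjusted over the list alone, with a median of −0.30 against −0.29 relative to LGDMEM. The list did not pass here (adjusted p = 0.0529, and adjusted p = 0.208 with an estimated correlation) but did in 6 of 17 alternative settings, so its calls do not set the 2 comparisons apart.

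ATF4 genes had 27 up and 1 down of 36 in Plasmax relative to HGDMEM (28 up and 1 down adjusted over the list alone, list adjusted p = 3.48e-13, adjusted p = 0.248 with an estimated correlation), with SLC7A11 up by 2.34, NARS by 1.12 and PSAT1 by 1.10. Cell cycle genes had 33 of 34 down (34 adjusted over the list alone, list adjusted p = 1.84e-29, adjusted p = 0.147 with an estimated correlation), among them CDC6 at −2.32, AURKA at −1.76 and UBE2C at −1.76. Fatty acid synthesis had 1 up and 10 down of 19, unchanged when adjusted over the list alone (list adjusted p = 7.38e-07, adjusted p = 0.137 with an estimated correlation), and p53 targets 9 of 24 up (11 adjusted over the list alone, list adjusted p = 0.000421, adjusted p = 0.248 with an estimated correlation), with BBC3 up by 1.59 and CDKN1A by 1.52. Mesenchymal transition genes had 6 up and 1 down of 14 (7 up and 2 down adjusted over the list alone, list adjusted p = 0.0011, adjusted p = 0.137 with an estimated correlation), with SERPINE2 up by 3.69, FN1 by 0.90 and CDH2 by 0.83. Metallothioneins had 5 of 9 down, unchanged when adjusted over the list alone (list adjusted p = 0.00109, adjusted p = 0.208 with an estimated correlation), with MT1G at −3.38, MT1F at −2.18 and MT1X at −1.26.

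Cytosolic ribosomal proteins had 14 of 48 up and 0 down (15 up adjusted over the list alone, list adjusted p = 0.00462, adjusted p = 0.57 with an estimated correlation), among them RPS18 at 0.92, RPL37 at 0.68 and RPL23 at 0.57, all genes with many processed pseudogenes. The number up was 8 without HGDMEM 1, HGDMEM 2 or Plasmax 1 and 9 without Plasmax 2. Mature hepatocyte genes had 3 up and 9 down of 26 (4 up and 9 down adjusted over the list alone, list adjusted p = 0.00872, adjusted p = 0.293 with an estimated correlation), with APOH at −1.57 and TF at −1.23. Chaperones had 8 of 21 down, unchanged when adjusted over the list alone (list adjusted p = 0.00901, adjusted p = 0.57 with an estimated correlation), with CRELD2 at −1.56, CALR at −1.21 and SEC61B at −0.80. Respiratory chain genes had 1 up and 12 down of 43, unchanged when adjusted over the list alone (list adjusted p = 0.021, adjusted p = 0.293 with an estimated correlation), with SDHB at −0.87 and NDUFA9 at −0.79, and this list was lost without HGDMEM 3 (adjusted p = 0.0583). Of the 2947 genes called, 1404 rose and 1543 fell, with 612 and 677 changed at least 2-fold.

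Across the Plasmax comparisons, 638 genes were higher and 923 lower in Plasmax than in each of the other 3 media, against 13.3 and 21.9 for independent lists of the same sizes. Of the genes called in any of these comparisons, 1 was called in opposite directions. These comparisons share the Plasmax libraries, which by itself makes calls coincide. For comparisons that share the EMEM libraries, 2 genes were called in the same direction in LGDMEM and HGDMEM, SAT2 up and MXRA8 down, 1 in LGDMEM and Plasmax, and 4 in HGDMEM and Plasmax, with 2 and 5 in opposite directions for LGDMEM and HGDMEM against Plasmax. Leaving out 1 library at a time, the overlaps in the same direction ranged from 0 to 4, from 0 to 51 and from 0 to 3, with the 51 without LGDMEM 1. In 20 simulations every library, the controls included, was drawn from the EMEM means, so that no group was changed, and the mean overlap was 0.05, 0.1 and 0. Simulated Plasmax was thus unchanged too, so the overlaps with it are no reference for the real ones, where Plasmax has many calls. Independent lists would share 0.00073 genes up and 0.0077 down for LGDMEM and HGDMEM, 0.20 and 0.73 for LGDMEM and Plasmax, and 0.40 and 1.69 for HGDMEM and Plasmax. Log2 fold changes against EMEM correlated across genes, which are not independent replicates, at 0.473 between LGDMEM and HGDMEM, 0.295 between LGDMEM and Plasmax and 0.112 between HGDMEM and Plasmax, where unchanged groups gave 0.5, 0.5 and 0.506. The covariances were 0.0857, 0.0986 and 0.0367 against simulated values of 0.065, 0.065 and 0.0654, differences of 0.0206, 0.0336 and −0.0287. The 3 EMEM libraries cannot be divided into parts of at least 2 each, so part of any excess may come from the shared controls.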

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

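The tests of a wrong label, a shared day, glucose supply, a share of abundant genes by library size, leukocyte RNA, scaling, hepatocyte genes and BMP-SMAD genes were chosen after the result they concern was seen. A signal appeared in data that the comparisons leave out. Of 601 rows without a gene symbol, 45 were called between Plasmax and EMEM, 30 higher and 15 lower (edgeR's quasi-likelihood test), which is 7.49% of them against 21.3% of named genes in the same fit. Between Plasmax and LGDMEM 55 such rows were called and between Plasmax and HGDMEM 58. In the other 3 comparisons the count was 0 with edgeR, and other tools were not run on these rows.

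HIF, ATF4 and chaperone genes were uneven among the LGDMEM libraries, and LGDMEM 3 exceeded LGDMEM 1 in the HIF target level by 1.29. After thinning all libraries to one total the difference was 1.25, against a range of 0.50 among EMEM libraries. The gap thus stayed at equal totals. LGDMEM 1 had the smallest total, 3995365, and LGDMEM 3 had 4574565. Thinning could therefore change little, and it is a weak test of depth. That LGDMEM 1 is a wrongly labelled EMEM or HGDMEM library is argued against by TXNIP, at 1.01 CPM there, 5.50 and 4.53 in the other LGDMEM libraries and 20.3 to 57.0 in the 6 EMEM and HGDMEM libraries. The upper exact Poisson bound in LGDMEM 1 was 2.59, which covers counting error only. A day shared by the libraries numbered 3 cannot be told apart, since the difference of number 3 from the other two was −0.19 in EMEM, 0.97 in LGDMEM, 0.59 in HGDMEM and 0.17 in Plasmax. Library names in the labels put Plasmax 1 last, so Plasmax numbers may not match those of the other media. Lower glucose in LGDMEM 3 than in LGDMEM 1 would lower TXNIP, which instead had 20 reads there and 4 in LGDMEM 1 (two-sided exact p = 0.00327, counting error only). The value runs against lower glucose but sets single libraries against counting error, so it decides nothing, and no other biological explanation within the medium was tested.

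The number of genes called between Plasmax and EMEM was weighed against technical causes. The deposited totals of named genes were alike, at 4883500 ± 732965 in EMEM and 4971740 ± 284475 in Plasmax, which argues against depth. Thinning to one total had little difference between these media to remove, so it adds no weight. It left 2352 genes called, 2253 of them called before in the same direction. Leaving out 13 mitochondrial transcripts and the 50 most abundant genes gave 2395 genes against 2394 outside them, but under TMM this moved log2 fold changes by a median of −0.0016 and so decides nothing. Under library size alone a larger share of a few genes acts on all others alike. These genes took 30.3% of the counts in EMEM and 31.1% in Plasmax, and leaving them out shifted the others by a median of 0.017 where the smallest called change was 0.23 in size, which argues against a few genes taking a larger share. The labels name HepG2 cells alone, so the design gives no source for RNA of leukocytes or stromal cells. The markers by themselves cannot decide this, because the leukocyte sum changed by −875 CPM but was 99.5% LYZ, and the other markers lay near the floor and went both ways. CD68 went from 2.24 to 5.77 CPM, CD14 from 3.93 to 3.56 and FCER1G from 2.22 to 1.78, and the stromal sum went from 12.2 to 11.2. The medium itself, the difference the design names, stays among the open explanations.

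TFRC and HAMP were lower in Plasmax than in EMEM. Under 3 other scalings the ratio of log2 fold change to SE nearest to 0 was −6.98, so the falls do not hang on the choice among these scalings. The scalings hardly differed, with a median log2 fold change over all genes of 0.015 in the main fit. It was 0.019 with RLE factors, 0.037 with library size only and 0.029 with upper-quartile factors. An error shared by all of them was therefore not tested. That HAMP fell with mature hepatocyte genes in general is argued against, since their median was −0.30 (quartiles −0.96 and 0.15), 2.34 above HAMP. The median was taken as the measure after the values were seen. The lowest list member, CYP8B1 at −1.33 (SE 0.77), lay 1.31 above HAMP. The SE of that difference was 0.86, so CYP8B1 cannot be told apart from HAMP. A fall together with some genes of hepatocytes is not excluded. FABP1 at −2.25, ORM2 at −2.30 and SULT2A1 at −2.03, picked for their values, lay within 2 SE of HAMP. Lower BMP-SMAD signalling is a candidate explanation that these data leave open, with ID1, ID3 and SMAD9 lower among 6 readout genes, so 3 of 6. A difference in iron supply between the media was not measured.

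Other splits of the libraries were counted for each number of called genes. Of 100 drawn splits of the 12 libraries into 4 groups, the real one included, 1 gave as many genes as the real 2506, and that was the real one. A random split thus seldom gives that count, but 100 splits cannot show a share below 1 in 100. The highest other split gave 2218 and also kept the Plasmax libraries together, as 2 of the 100 did, and the highest with Plasmax apart gave 16. The test therefore shows mainly that the Plasmax libraries are alike, which replicates that may be technical would also give. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The number of splits as large, the real count and the highest other were 1, 18 and 1 for HGDMEM against EMEM, 1, 2417 and 0 for Plasmax against EMEM, and 1, 7 and 6 for HGDMEM against LGDMEM. They were 1, 2321 and 0 for Plasmax against LGDMEM and 1, 2947 and 2 for Plasmax against HGDMEM. For LGDMEM against EMEM they were 2, 8 and 81, and the split with 81 set LGDMEM 1, EMEM 1 and EMEM 3 against LGDMEM 2, LGDMEM 3 and EMEM 2, which points to a structure of the samples other than the media.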

How the results depend on the processing

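Among the genes named by the fixed rule and the list tests, no called result changed sign or test direction in any alternative. Other called genes were not checked for sign. The median of the NRF2 list between LGDMEM and EMEM, which is not the test itself, turned slightly negative without LGDMEM 2. The number of genes called for Plasmax against each other medium stayed within 1.5 times except at the stricter adjusted p. Of the parts of that number, the genes higher in Plasmax than in EMEM were 714 without EMEM 1 against 1094. The numbers of lists past the threshold moved more and are given below. The rows without a symbol and the block within HGDMEM pairs were chosen after seeing the data. A sign change of a value called in neither setting was counted as no change. The planned fit without a filter was void, since the filter removed no gene. The cause was not tested for any value below, apart from the stricter p, where fewer calls follow from its construction. At an adjusted p of 0.01 the counts were 1419 among the 4 media, 2 for LGDMEM and 2 for HGDMEM against EMEM, and 1290, 1254 and 1711 for Plasmax against EMEM, LGDMEM and HGDMEM, and the overlaps fell to 0, 0 and 0. DESeq2 called 65, 68 and 55 genes for LGDMEM and HGDMEM against EMEM and HGDMEM against LGDMEM, of which 52.3%, 25% and 18.2% were higher, with 3185 adjusted p missing in the last. Limma voom called 4 for HGDMEM against LGDMEM. Fits to the compared media alone gave 2 for LGDMEM against EMEM, 43 for HGDMEM against EMEM and 2 for HGDMEM against LGDMEM. With the rows without a symbol LGDMEM and HGDMEM against EMEM gave 2 and 11.

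With the replicate block HGDMEM against LGDMEM gave 15 genes and, within the pair of media, 3, and HGDMEM against EMEM gave 73 within the pair. LGDMEM against EMEM, which failed the pairing rule at number 3 alone, gave 15. Apart from the cholesterol list between HGDMEM and LGDMEM, the block changed no list call of the paired comparisons.

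Overlaps of calls (LGDMEM and HGDMEM, LGDMEM and Plasmax, HGDMEM and Plasmax, all against EMEM) were 12, 25 and 15 with DESeq2 and 4, 2 and 1 with library size only. The overlap of LGDMEM and Plasmax was 2 with RLE factors and 4 with the block. In fits to the media alone, LGDMEM and HGDMEM gave 1 and HGDMEM and Plasmax 11. With the rows without a symbol they were 1, 0 and 1. Lists past the threshold with an estimated correlation were 0, 0, 1, 0, 1 and 1 in the order LGDMEM, HGDMEM and Plasmax against EMEM, HGDMEM against LGDMEM, Plasmax against LGDMEM and Plasmax against HGDMEM, and with fry 0, 2, 16, 0, 24 and 17.

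Leaving out 1 library at a time, the counts ranged from 1685 to 2749 among the 4 media and, in the same order of comparisons, from 2 to 87, 1 to 7, 1693 to 2109, 4 to 118, 1666 to 2265 and 2256 to 2434. The 87 and the 118 came without LGDMEM 1, the 2 without EMEM 1, the 4 without LGDMEM 2 and the 1 without HGDMEM 2. Overlaps ranged from 0 to 4, 0 to 51 and 0 to 3, and lists past the threshold from 8 to 11, 2 to 7, 8 to 9, 9 to 10, 12 to 16 and 10 to 13. In simulation 12 of 67 changes of 1.5-fold were recovered between Plasmax and EMEM, and what limits them was not tested. The simulation changed far fewer genes than were called in the real data, so this share does not carry over.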

Other observations

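The test of glucose-responsive genes was chosen after the result was seen, and so were the genes named here. Several genes of growth factors, adhesion and membrane proteins were called higher in Plasmax than in EMEM, and since they were picked for their values they say nothing about such genes as a group. AREG, a ligand of the EGF receptor, went from 16.2 ± 3.25 to 137.8 ± 23.3 CPM (SD, n = 3, log2 fold change 3.08), the laminin chain LAMB3 rose by 4.00, GPRC5A by 3.98, EMP1 by 3.97, CD109 by 2.98 and the integrins ITGA3 and ITGA2 by 2.59 and 1.28. EREG, another EGF receptor ligand, had 55 reads in Plasmax and 0 in EMEM, at least 17.8-fold higher against a floor of 3 counts over the EMEM libraries. HBEGF at 0.97 and TGFA at 0.59 were not called.

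Of 19 histone genes, those with symbols that begin with HIST, H1F or H2A, 5 were called higher and 6 lower in Plasmax than in EMEM. Histone genes with other symbols were not looked at. H1F0 rose by 1.11, HIST1H1C by 1.69 and HIST2H2BE by 2.61, while H2AFX fell by 1.72 and H2AFZ fell by 0.59 on the log2 scale. Histone genes are similar in sequence, so their counts are uncertain. Some were also low, such as HIST2H2BE at 3.99 CPM in EMEM and 24.2 CPM in Plasmax. Among single genes, the selenoproteins GPX3 at −1.77 and SELENOP at −0.94 fell, SELENOW rose by 1.35, and the immediate early gene EGR1 and the phosphatase DUSP5 rose by 1.86 and 2.97. G0S2, an inhibitor of lipolysis, had 160 reads in Plasmax and 0 in EMEM, at least 51.6-fold higher against the same floor.

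TXNIP and its relative ARRDC4 (1 read in EMEM and 115 in Plasmax) were higher in Plasmax, for which a rise of glucose-responsive genes in general was a hypothesis. The upper quartile of the log2 fold change over the other 15 members of that list was 0.35, with 3 called higher and 4 lower, so these members did not rise together. The list also holds gluconeogenesis genes, and between HGDMEM and LGDMEM TXNIP alone of its members was called. The other members are thus weak readouts of glucose here, and the test cannot decide on a glucose response of TXNIP and ARRDC4.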
